A study of Drosophila melanogaster with 4 samples.

How the data were processed

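The samples were 4 libraries from S2-DRSC cells treated with double-stranded RNA against GFP: 2 H2Av immunoprecipitations and 2 inputs, grouped and numbered by their titles. Per the labels' protocols, cells took up 50 µg of double-stranded RNA in a first round and 200 µg in a second, were fixed with formaldehyde and sonicated, and H2Av was precipitated with an affinity-purified rabbit polyclonal antibody, number 9751, raised against a peptide. The description field of replicate 2 of the immunoprecipitation reads as input and that of replicate 1 of the input names the antibody, while the titles and source names of all 4 agree, and the titles were followed.

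What the authors deposited and what was analysed here were 3 lists of significantly enriched regions with start, end and a score: one for each immunoprecipitated library and one for the replicate set. No list of the input libraries was used here. Bowtie 0.12.7 is named per the submitters' processing notes, and the genome build is FlyBase release 5 per the file headers. The peak caller, its threshold, the use of the input, the treatment of reads with several matches, and whether the combined list came from pooled reads or from joined calls are not given in the sources used here. The score of each region is the authors' own value, deposited without a stated scale, and was used only to rank, filter and describe regions within a list or across matched regions. Per the file headers the lists are on the same build, and arm lengths were taken from there. Because the only gene table at hand is of release 6, the planned analyses of gene starts, gene bodies and gene lists were not run, and regions are given by position. Replicate 2 also held 1 record typed as a depleted region, at 3417313 to 3419170 on 3L, which was left out. The lists carry no read counts, so depth is unknown, and the intervals given for shares of regions cover counting error only, with regions treated as independent.

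Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with plots from matplotlib 3.10.9. The main analyses covered the arms 2L, 2R, 3L, 3R, 4 and X (120.4 Mb). Regions counted as shared when they overlapped by at least 1 bp, and matched pairs were each other's largest overlap. Overlap between replicate lists was tested against 100000 circular shifts of one list within each arm, sampled every 10 bp, which keep widths and spacing. The share of an arm in the covered sequence was tested against 100000 circular shifts along the joined arms, two-sided, with Benjamini-Hochberg adjustment over the 6 arms. Proximal windows of 1.5 Mb (the end of 2L, 3L and X and the start of 2R and 3R) were tested by shifts within the arm, two-sided, adjusted over 5 arms. Median scores by chromosome were tested by all rotations of the scores along the ordered regions. All these are tests of placement within a list, not across cultures. Neighbouring shifts cover almost the same sequence, so the shifts are not independent placements.

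The tests were tested on simulated data, with lists made from the 3974 regions of replicate 1 and fewer shifts. With regions placed at random, the overlap test gave p under 0.05 in 0 of 20 simulations, and with a random 10% of the other list planted it did so in 20 of 20. The chromosome 4 share was called in 0 of 20 simulations at ordinary density and in 20 of 20 when filled more densely. That filling added regions to all those of replicate 1 on chromosome 4, so detection of the observed excess was not measured. Random placement also lacks the clustering of the real lists. Random spacing of replicate 1 gave a mean of 89.0 stretches of at least 100 kb without regions, against 287 observed. False calls in lists so clustered were not measured. The proximal test was called in 1 of 20 random placements and in 20 of 20 with a filled window. The score rotation was called in 0 of 20 shuffles and in 20 of 20 with scores on chromosome 4 lowered by 0.5. Shuffling removes the order of scores along the arms, which the rotation test keeps in the real lists. In replicate 1 in its real order, a median difference of -0.66 on chromosome 4 gave a rotation p of 0.042 before adjustment. Detection of a drop of 0.5 in the real lists was therefore not measured.

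The designs and alternatives were fixed before the data were examined, except those named as added. The rule for named regions, fixed for the case without an annotation of the same build, took the 2 widest and the 2 highest-scoring combined-list regions of each arm. Alternatives were the regions at or above the median score of a list, Het scaffolds and chromosome U included, regions within 200 bp merged, 50% reciprocal overlap, each replicate list alone in place of the combined list, and the sequence called in both replicates. Added after seeing the data were the proximal windows, the score tests by chromosome, the tests of arms other than X and 4, the score limit of 1 and the count of long stretches without regions. So were the tests of the width and score of combined-only regions, of joining on chromosome 4 and of the Het scaffolds. The bound for chance placement on chromosome 4 was also set then.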

Results

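H2Av, the histone H2A variant that serves Drosophila melanogaster as both its H2A.Z and its H2A.X, was profiled by chromatin immunoprecipitation and sequencing in S2-DRSC cells, a male, embryo-derived cell line. All cells had received double-stranded RNA against GFP, a gene that flies lack, so the profile is that of a control RNAi culture. The series holds 2 immunoprecipitated libraries and 2 libraries of input chromatin. No other RNAi target or antibody was analysed here, and the comparisons made are between the replicates, between each replicate and the list made for the replicate set, and between chromosomes. The authors' list for replicate 1 held 4198 enriched regions, that for replicate 2 held 4070, and the list for the replicate set, called the combined list here, held 4698. Read depth is unknown because the lists carry no counts, and the spread between the replicates may be technical, since no label says that they came from separate cultures. Positions are those of FlyBase release 5. Genes, exons and promoters at these positions were not analysed here, because the gene table at hand is of release 6.

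Across the 6 arms 2L, 2R, 3L, 3R, 4 and X, H2Av was enriched in regions of a few kilobases. Replicate 1 had 3974 regions covering 18.1 Mb, or 15.0% of the arms, and replicate 2 had 3867 regions covering 17.5 Mb, or 14.5%. Median widths were 3.57 kb (interquartile range 2.64 to 5.44) in replicate 1 and 3.59 kb (2.68 to 5.40) in replicate 2. The combined list had 4341 regions on these arms, with a median width of 3.67 kb (2.36 to 5.88), and covered 20.9 Mb or 17.3%.

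The first comparison asked how far the replicates placed H2Av at the same positions. Of the 3974 regions of replicate 1, 3652 overlapped a region of replicate 2 by at least 1 bp (91.9%, 95% Wilson interval 91.0 to 92.7). Of the 3867 regions of replicate 2, 3702 overlapped replicate 1 (95.7%, 95.05 to 96.3). The sequence called in both lists came to 16.6 Mb of the 18.9 Mb called in either, or 87.8%. Shifting one list along each arm gave a mean of 2.72 Mb in common, or 8.30%, and none of the 100000 shifts reached the observed overlap (one-sided permutation test, p = 1e-05, the smallest that this number of shifts can give). The edges of matched regions lay close together, with median distances of 95 bp between starts and 96 bp between ends over 3555 matched pairs. The authors' scores of these pairs correlated with a Spearman rho of 0.965 and a Pearson r of 0.971, a correlation across regions, which are not independent replicates. The score was higher in replicate 2 in 76.5% of the pairs, with medians of 1.92 in replicate 2 and 1.79 in replicate 1. The 322 regions found only in replicate 1 had a median score of 0.64 and a median width of 1631 bp, against 1.78 and 3749 bp for its matched regions. The 165 regions found only in replicate 2 had a median score of 0.64 and a median width of 1555 bp, against 1.90 and 3678 bp.

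The second comparison set the combined list against the replicate lists. Of its 4341 regions on the arms, 3345 overlapped a region in both replicate lists (77.1%, 95% Wilson interval 75.8 to 78.3), and these made up 91.7% of its covered sequence. Another 388 regions (8.94%, 8.13 to 9.82) overlapped one replicate list only. The remaining 608 (14.0%, 13.01 to 15.1) overlapped neither, and they held 4.22% of the covered sequence. In the other direction, 3963 of the 3974 regions of replicate 1 and all 3867 of replicate 2 overlapped the combined list. Regions in both replicates had a median combined score of 1.78 and a median width of 4279 bp. Those in one replicate list only had a median score of 0.44 and a median width of 1934 bp. Those in neither had a median score of 0.44 and a median width of 1315 bp. Among regions at or above the median score of the combined list, 99.6% were in both full replicate lists and 0.37% in neither. The combined list was made for the set of these same replicates, so it is not independent of their lists. Its overlap with them is a description and not separate support.

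The distribution of scores had 2 peaks in each of the 3 lists. In the combined list, bins of 0.2 score units peaked at 725 regions between 0.4 and 0.6 and again at 468 between 2 and 2.2, with 167 between 1 and 1.2. In replicate 1 the peaks held 426 regions between 0.6 and 0.8 and 484 between 2 and 2.2, with 196 between 1 and 1.2. In replicate 2 they held 356 and 487 regions in these bins, with 171 between 1.2 and 1.4. Regions scoring below 1, a limit set after the scores were seen, were 36.2% of the combined list (95% Wilson interval 34.8 to 37.6), 24.4% of replicate 1 (23.1 to 25.7) and 21.7% of replicate 2 (20.5 to 23.1). Low-scoring regions were narrow: their median width was 1969 bp in the combined list against 4657 bp above the limit, 1998 against 4096 bp in replicate 1, and 2000 against 4003 bp in replicate 2. The score's scale is not given in the sources used here, so whether it measures a fold is unknown, and the shares below 1 describe each list and are not compared between lists.

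**Figure D1:**
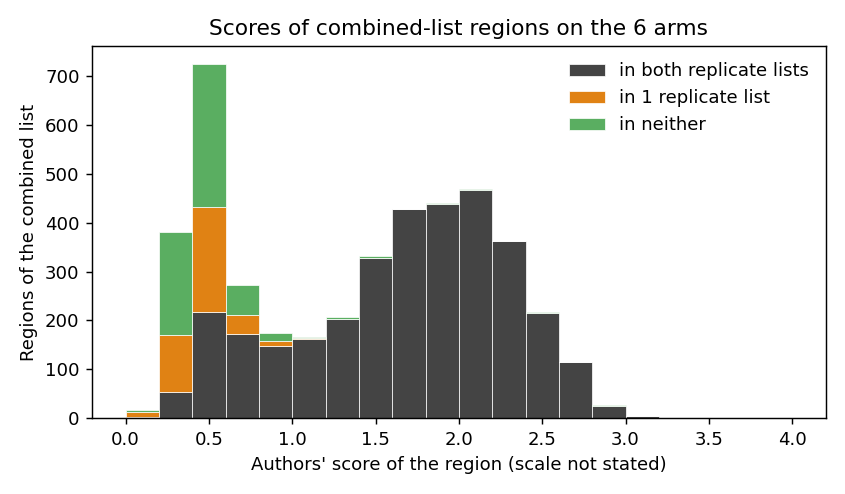
Number of combined-list regions on the 6 arms (vertical axis) in bins of 0.2 of the authors' score (horizontal axis, scale not stated), coloured by whether a region overlaps both replicate lists, 1 of them or neither. Regions in neither list, 608 in all, lie mostly at low scores, with 96.9% below 1, and 466 of the 468 regions scoring between 2 and 2.2 were found in both replicates.

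The third comparison concerned chromosomes. Chromosome 4, a small and largely heterochromatic chromosome that nevertheless carries active genes, had the densest H2Av calls. Enriched regions covered 47.5% of it in the combined list, 38.2% in replicate 1 and 36.9% in replicate 2 (37.6% ± 0.9, SD, n = 2 replicate lists). The other arms lay between 12.6% and 20.4% in all lists. Chromosome 4 makes up 1.12% of the arms' length and held 3.07% of the covered sequence in the combined list, which is 2.74 times its share by length. This excess passed the circular-shift permutation test in the combined list (two-sided p = 0.00145, 0.0087 after Benjamini-Hochberg adjustment over 6 arms), in replicate 1 (p = 0.0011, adjusted 0.0066) and in replicate 2 (p = 0.00076, adjusted 0.00456). The regions were more frequent, at 88.0 per Mb against 35.5 on the other arms in the combined list. Median widths on chromosome 4 and on the other arms were 3581 and 3673 bp in the combined list, 3564 and 3569 bp in replicate 1, and 3776 and 3591 bp in replicate 2. Mean widths were larger on chromosome 4 in all 3 lists, at 5392 against 4793 bp in the combined list, and these widths were not tested. Among regions at or above the median score, chromosome 4 held 1.80% of the covered sequence in the combined list, and the excess no longer passed the permutation test (p = 0.083). In the replicate lists such regions covered 10.5% and 10.0% of chromosome 4, against 9.62% and 9.13% of the other arms (permutation p = 0.76 and 0.77).

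**Figure D2:**
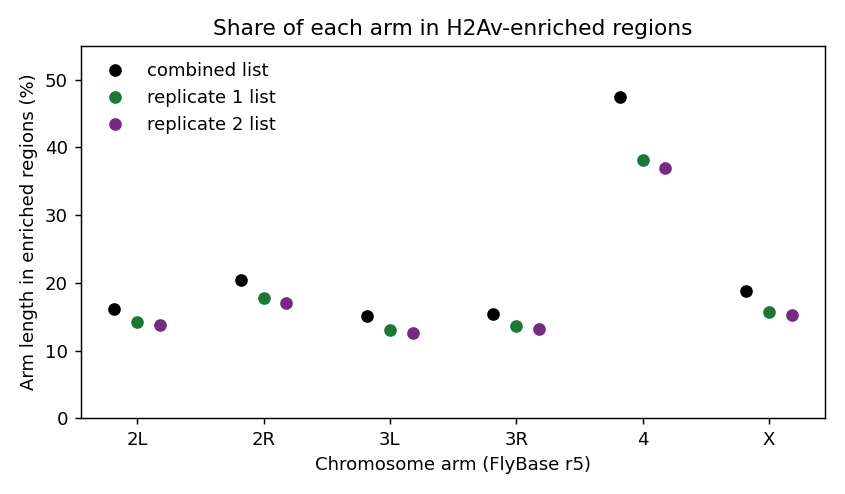
Percentage of each chromosome arm's length (vertical axis) inside enriched regions for the combined list and for each replicate list (points, 1 per list). Chromosome 4 stands at 36.9% to 47.5%, above every other arm in all 3 lists.

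The X chromosome, which the dosage compensation complex upregulates in male cells, held a share of the covered sequence within the range of the shifts. Regions covered 18.8% of X in the combined list and 15.5% ± 0.3 (SD, n = 2) in the replicate lists, against 16.6% and 14.3% ± 0.4 for 2L, 2R, 3L and 3R together. X held 20.2% of the covered sequence in the combined list with 18.6% of the arms' length (two-sided permutation test over circular shifts, p = 0.46, adjusted 0.55). The values in the replicate lists were 19.5% (permutation p = 0.69) and 19.6% (permutation p = 0.65). No excess on X was planted in the simulations, so how large a difference this test would detect is unknown. These p values do not show that X equals the other arms. 2R had the highest coverage after chromosome 4, with 20.4% in the combined list, and held 20.7% of the covered sequence for 17.6% of the length (permutation p = 0.11, adjusted 0.24). 3L and 3R held 17.7% and 20.5% of the covered sequence for 20.4% and 23.2% of the length, and neither passed the permutation test (adjusted p = 0.24 for both). Tests of arms other than X and 4 were added after the lists were seen.

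The scores of chromosome 4 were at the low end. Its median in the combined list was 0.69 against 1.56 on the other arms, in replicate 1 it was 1.07 against 1.73, and in replicate 2 it was 1.05 against 1.88. Rotating the scores along the ordered regions gave two-sided permutation p values of 0.059, 0.042 and 0.037, each 0.12 after adjustment over the 6 tests made. Median scores on X were 1.42 in the combined list, 1.68 in replicate 1 and 1.82 in replicate 2, against 1.57, 1.72 and 1.88 on the other arms (permutation p = 0.29, 0.70 and 0.65). These score tests were chosen after the lists were seen.

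**Figure D3:**
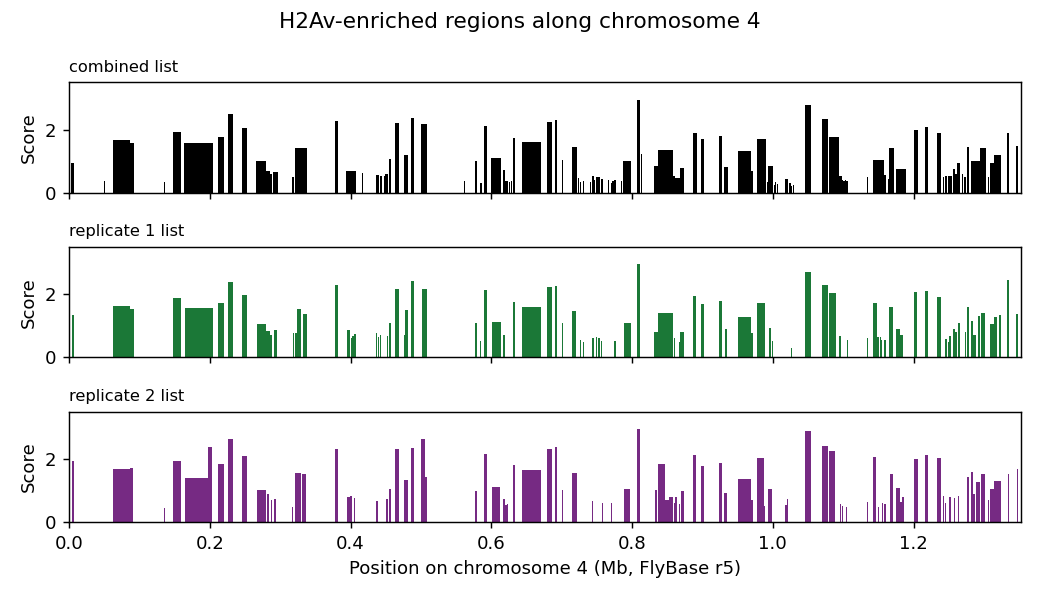
Enriched regions along chromosome 4 (horizontal axis, Mb, FlyBase release 5) in the combined list and each replicate list; bar width is the region's extent and bar height the authors' score. Wide regions at 163952 to 204222 and 643960 to 670324 in the combined list recur in both replicates, and the combined list has 119 regions there against 101 and 98.

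Coverage was also compared between the sequence beside the centromere and the rest of each long arm, a comparison chosen after the lists were seen. On 2L, the 1.5 Mb nearest the centromere was 43.1% covered in the combined list against 14.3% of the rest (permutation test over circular shifts, p = 0.011, 0.027 after adjustment over 5 arms). On 2R it was 39.4% against 19.0% (permutation p = 0.00375, adjusted 0.019). Shifts of a 1.5 Mb window along an arm overlap heavily, so these p values do not count independent placements. Replicate 1 gave 33.6% on 2L and 32.7% on 2R, and replicate 2 gave 31.0% and 29.3%, and all 4 passed the permutation test with adjusted p values between 0.020 and 0.039. On 3R the window was 25.9% covered against 14.7% (permutation test, adjusted p = 0.030). The replicate lists gave 22.1% against 13.1% and 21.1% against 12.7%, but did not pass (permutation test, adjusted p = 0.055 and 0.058). 3L at 21.2% against 14.7% and X at 16.1% against 18.9% did not pass (permutation test, adjusted p = 0.20 and 0.63). On 3L the replicate lists gave 14.9% against 12.9% and 13.3% against 12.5%. With a window of 1 Mb none of the 5 arms passed in the combined list: 2L was 43.4% covered and 2R 37.2% (permutation test, adjusted p = 0.075 for both, p = 0.023 and 0.030 before adjustment), and 3R 20.4% (adjusted p = 0.54). Proximal regions scored low on 2L, 2R and 3L, with combined-list medians of 0.46, 0.78 and 0.64 against 1.62, 1.62 and 1.64 on the rest of each arm. In the combined list the medians were 1.46 against 1.72 on 3R and 1.03 against 1.43 on X, but in replicate 2 they were 1.94 against 2.00 on 3R and 1.83 against 1.82 on X, and none of these score differences was tested.

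**Figure D4:**
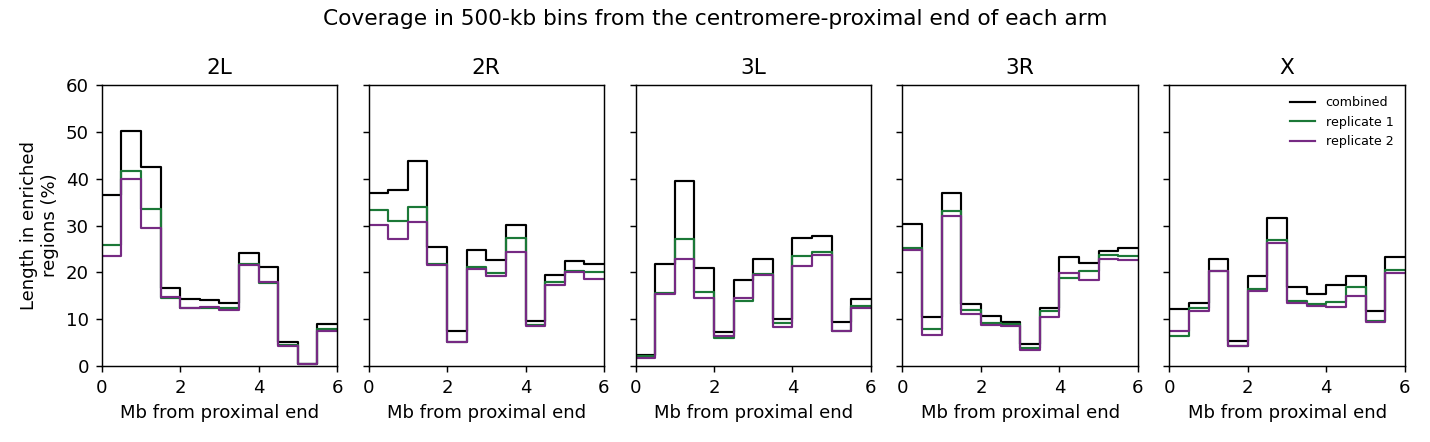
Percentage of sequence inside enriched regions (vertical axis) in 500-kb bins counted from the centromere-proximal end of each long arm (horizontal axis, Mb), for the combined list and each replicate list (lines). On 2L the first 3 bins hold 36.6%, 50.2% and 42.5% in the combined list and the next 16.6%, while on 3L the first bin holds 2.38% and the third 39.4%.

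The widest and the highest-scoring regions of each arm were taken from the combined list, 2 of each kind per arm. The widest region of all lay on 3L from 16569382 to 16610574, spanning 41.2 kb with a score of 2.48. Replicate 1 covered 98.2% of it with 2 regions and replicate 2 covered 97.4% with 4. The next was on chromosome 4 from 163952 to 204222, spanning 40.3 kb with a score of 1.57, called as 1 region in replicate 1 and as 2 in replicate 2. On 2L, the region from 10416886 to 10452164 spanned 35.3 kb and scored 2.15, and the one from 22167150 to 22200868, in the proximal 1.5 Mb, spanned 33.7 kb and scored 1.16. On X, the region from 8034222 to 8065322 spanned 31.1 kb with a score of 2.22, and the one from 1748268 to 1776492 spanned 28.2 kb with a score of 2.32. The 2 widest regions of 2R, from 952590 to 980228 and from 36872 to 62698, both lay beside the centromere, with widths of 27.6 and 25.8 kb and scores of 1.62 and 0.88. The second widest of chromosome 4, from 643960 to 670324, spanned 26.4 kb with a score of 1.62. On 3R the widest regions ran from 5578498 to 5605258 (26.8 kb, score 2.41) and from 7050684 to 7071666 (21.0 kb, score 2.34). The second widest of 3L ran from 832248 to 855706 (23.5 kb, score 2.09). Each of these was found in both replicate lists.

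The highest-scoring regions were narrower, from 3.28 to 10.1 kb apart from 1 of 1001 bp on 3L. The highest combined score on the arms, 3.41, belonged to a 3.81 kb region on 2R from 3164090 to 3167898. It was called from 3164334 to 3167798 with a score of 3.36 in replicate 1 and from 3164101 to 3167808 with 3.65 in replicate 2. On 3R, the region from 4385692 to 4391842 scored 3.24, with 3.23 and 3.34 in the replicates, and the one from 23095486 to 23102462 scored 3.20, with 3.05 and 3.38. On X, the region from 19544478 to 19547756 scored 3.11 and the one from 11260700 to 11265544 scored 2.97. The second region of 2R, from 810126 to 813526, scored 3.04. On 2L, those from 19734044 to 19738234 and from 18687380 to 18691404 scored 2.95 and 2.92. On chromosome 4, the regions from 806728 to 811208 and from 1045606 to 1054594 scored 2.93 and 2.79. On 3L, the region from 19792028 to 19802152 scored 2.97 and was found in both replicates, as were all those above. The top score on 3L, 2.98, came from a region of 1001 bp at 49188 to 50188 that overlapped no region in either replicate list.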

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

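Outside the 6 arms that the comparisons used, the combined list held 357 regions on the Het scaffolds and chromosome U, the assembly's heterochromatic and unplaced sequence, which is signal in data left out of the main measurement. A list of this kind can hold such regions anywhere, so their presence tests nothing, and they covered 6.18% of that sequence against 17.3% of the arms. The replicate lists held 224 and 203 there. Coverage in the combined list was highest on XHet at 25.8%, followed by 3LHet at 14.0%, 2RHet at 10.2% and 2LHet at 8.60%, with 4.22% on 3RHet, 3.01% on U and 2.52% on YHet. Of the 357 regions, 166 (46.5%) were found in both replicate lists and 134 (37.5%) in neither. The highest score of the whole combined list, 3.45, belonged to a region of 2699 bp on 2RHet from 1151452 to 1154150. The 4 regions on YHet had a median score of 2.31. Medians were 1.29 on U, 0.94 on 2LHet, 0.79 on XHet, 0.70 on 3RHet and 0.69 on 2RHet and 3LHet.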

How the results depend on the processing

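The proximal windows, the score tests by chromosome, the score limit and the count of long stretches, with their alternatives, were chosen only after the result was seen. The overlap of the replicate lists, 87.8% of the sequence called in either, ranged from 83.4% to 87.8% over 3 alternatives, each with a permutation p of 1e-05. That is the smallest p that the shifts can give, so it cannot tell the alternatives apart. With 50% reciprocal overlap, which admits fewer matches by construction, 87.6% of replicate 1 regions were found in replicate 2 and 90.02% the other way, and 72.1% of combined-list regions were in both replicates and 16.5% in neither. With both replicate lists limited to regions at or above their own median score, 94.8% of replicate 2 regions were found in replicate 1, a set with fewer regions to match by construction. Of combined-list regions at or above the median score, 99.6% were in both full replicate lists and 0.368% in neither; the cause was not tested. In that combined-list set the share of chromosome 4 was 1.80% (permutation p = 0.083), and the cause was not tested. In the other 5 alternatives, none of which filters by score, it passed, at 2.75% to 3.08%. With the score filter on the replicate lists, coverage of chromosome 4 was 1.09 times that of the other arms in both (permutation p = 0.76 and 0.77). The share of X stayed between 19.1% and 20.2% in all 6 alternatives (permutation p from 0.34 to 0.75). Leaving out a replicate, by using the other one's list, gave 2.86% on chromosome 4 both times and 19.5% to 19.6% on X. With a proximal window of 1 Mb, 2L, 2R and 3R no longer passed after adjustment, and with either replicate list alone 3R did not; the cause was not tested. The alternatives planned for gene starts, gene bodies and gene lists were not run, as no release 5 annotation was used here. No paired analysis was possible because no list of the input libraries was used here, so the groups have no values to pair. Read depth, which limits how weak a region can be called, is unknown.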

Other observations

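The tests of long stretches without regions, of the width and score of combined-only regions, of joining on chromosome 4, and of the Het scaffolds were chosen only after the result was seen; the share test of chromosome 4 was planned, but its bound for chance placement was set after its result was seen. Long stretches of the arms held no H2Av region at all. The combined list left 272 stretches of at least 100 kb without a region, 48.1 Mb or 39.9% of the arms, where random spacing of the same regions gave 62.1 ± 6.7 stretches (SD over 1000 placements) and at most 84 (permutation p = 0.001, the smallest these placements can give). The replicate lists had 287 and 286, against 89.0 and 96.6 at random (permutation p = 0.001 for both). With a minimum of 50 kb the combined list had 562 stretches against 498.9 (permutation p = 0.001), but the replicate lists had 581 against 573.9 and 587 against 593.0 (p = 0.31 and 0.69). The longest spanned 640 kb on 2L from 14364033 to 15003613, and others spanned 569 kb on 2R from 15562529 to 16131281, 421 kb on 3L from 22283309 to 22703981, 399 kb on 3R from 2488023 to 2887143 and 353 kb on X from 7219689 to 7572467. Chromosome 4 had no stretch of 100 kb, its longest in the combined list being 53.1 kb. Whether unmappable sequence lies in these stretches was not tested.

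The 608 combined-only regions came from a list that differs in form: all 4698 of its starts and ends are even numbers, against 48.3% of starts in replicate 1 and 49.3% in replicate 2, and its narrowest region has 1001 bp against 1301 and 1304 bp. Of the 608, 290 (47.7%, 95% Wilson interval 43.8 to 51.7) were narrower than 1301 bp, short of the 90% set as the bound. This cannot show that a lower width minimum accounts for only part of them, because a region can be narrower in the replicate lists. The region from 806728 to 811208 on chromosome 4 spanned 4.48 kb in the combined list, against 3.93 kb in replicate 1 and 3.90 kb in replicate 2. The median width of the 608 was 1315 bp. Fragments split from the edge of replicate regions are argued against as the main source, as 28.5% (25.0 to 32.2) lay within 1000 bp of one, below the bound of 50%. Weaker enrichment admitted by the combined list stays open, as the scale of the score is not given in the sources used here. Of the 608, 19 scored at least 1, and 15 of these were narrower than 1301 bp. The median score of the 608, 0.44, lay below the list's lower quartile of 0.58, but it was known before that bound was set. It does not set them apart either, as the 388 regions found in 1 replicate list also had a median of 0.44, with 99.7% below 1. Whether pooled reads or another threshold let the 608 in stays open, and no biological explanation was tested.

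For the high coverage of chromosome 4, the shift test argues against chance placement (largest permutation p over the lists, 0.00145), within limits. The combined list was made for the same replicates, neighbouring shifts overlap, and false calls in lists so clustered were not measured. Joining into wide blocks is argued against as the whole cause, as chromosome 4 had at least 1.93 times as many regions per Mb as any other arm. Low-scoring regions alone as the source of the high coverage of chromosome 4 stay open. Among regions at or above the median score, its coverage was 1.61 times that of the other arms in the combined list, 1.09 times in both replicate lists, and none passed the permutation test (p = 0.083, 0.76 and 0.77), while among regions below the median it was 5.36, 5.40 and 5.26 times. No biological explanation was tested. Copy number, mappability and the authors' use of the input could raise low-scoring calls there too, and none of these was tested.

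The high coverage beside the centromere of 2L and 2R passed its adjusted threshold with a window of 1.5 Mb (43.1% and 39.4%). It did not pass with 1 Mb (43.4% and 37.2%, adjusted permutation p = 0.075 for both). On 2L, joining into wide blocks is argued against as the whole cause, as the window held at least 2.13 times as many regions per Mb as the rest in the 3 lists (largest permutation p, 0.013). On 2R this could not be told: the ratio was 1.53 in the combined list, 1.36 in replicate 1 and 1.21 in replicate 2 (permutation p = 0.035, 0.084 and 0.24). Weak regions as the only source stay open: coverage by regions at or above the median score was 1.19, 1.29 and 1.05 times that of the rest on 2L in the combined list, replicate 1 and replicate 2 (permutation p = 0.60, 0.44 and 0.90), and on 2R it was 1.52, 1.78 and 1.35 times (permutation p = 0.10, 0.0255 and 0.22), where replicate 1 alone goes against it, while coverage by regions below the median was 7.92, 5.17 and 5.19 times that of the rest on 2L and 3.44, 2.35 and 2.70 times on 2R (largest permutation p, 0.015). A property shared by all heterochromatic sequence cannot be judged either: the Het scaffolds together were 9.62% covered against 41.3% in the 2 windows, but how reads with several matches were placed there is not given in the sources used here, and no biological explanation was tested.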
